A study of Caenorhabditis elegans with 8 samples.

How the data were processed

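RNA sequencing libraries were made from total RNA of sorted Caenorhabditis elegans neurons. The worms were of strain OH10689, which carries otIs355, a reporter in which a promoter of the neuronal gene rab-3 drives a nuclear red fluorescent protein, and cells were collected by fluorescence-activated sorting. There were 4 RNA samples. Each was divided between the SoLo Ovation kit and the SMARTseq V4 kit, the latter followed by Nextera XT, which gave 8 libraries, 4 per kit, numbered 1 to 4 in each kit. As background, SMARTseq V4 starts cDNA synthesis from the poly(A) tail with an oligo-dT primer and does not mark the strand, whereas the SoLo chemistry does not depend on a poly(A) tail and removes ribosomal RNA fragments after library synthesis. The labels do not say whether the 4 RNA samples came from separate cultures or sorts, so p-values measure the spread between these RNA samples, which may be technical.

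The authors deposited raw counts of reads per gene, 1 column per library, not normalised. STAR, SAMtools and featureCounts, with genome build WBcel235, are named in the submitters' processing notes, without versions, roles or settings. The strand setting, the treatment of reads with several alignments, the use of molecular identifiers and the annotation release are not given in the sources used here. Without the strand setting, reads of a gene and of an overlapping gene on the opposite strand cannot be told apart, and without the alignment setting reads of near-identical gene copies may have been split or dropped, so values of such genes are uncertain. The table held 46748 genes, and 0 columns belonged to no listed sample. Library totals lay between 2354681 and 7099497 counts. Without molecular identifiers, reads are not independent molecules, and intervals and floors given for counts cover counting error only.

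Gene names were matched to the Ensembl release 115 annotation of WBcel235, directly or through tables of gene names and synonyms. A match was found for 45672 genes, which held 96.8% of all counts, and 1076 genes, among them the 12 mitochondrial protein-coding genes, stayed without a biotype, length or position. Non-coding genes are matched genes whose annotated biotype is not protein-coding, pseudogenes included. Coordinates are 1-based on WBcel235. Exonic length is the union of all annotated exons, and 100% of the tested protein-coding genes had one.

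Differential abundance between the kits was tested on the deposited counts with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM normalisation, filterByExpr by kit, all 8 libraries in 1 fit without a replicate block, and Benjamini-Hochberg adjustment over the 11378 genes that passed the filter. Genes with an adjusted p under 0.05 were called. CPM values were computed here with the TMM factors. Standard errors of log2 fold changes were obtained as the absolute log2 fold change over the square root of the F statistic, an approximation. Where a gene had 0 reads in 1 kit, its fold change was bounded with a floor of 3 counts over the 4 libraries of that kit together, which is 0.224 CPM in SoLo and 0.154 CPM in SMARTseq. Where it had 1 to 3 reads in 1 kit, the ratio of summed reads per effective library is given with its 95% Clopper-Pearson interval. Both rules were also applied, after the data were seen, to genes left with so few reads in a kit when 1 library was left out, over its remaining libraries. Tested on simulated data made from the means, estimated dispersions and library sizes of SoLo against SMARTseq, with 10963 genes in the step, the fit called 52% of 100 genes changed 4-fold, 6% of 100 genes changed 2-fold and 0.02% of 10777 unchanged genes. Far fewer genes were changed there than the 5415 called in the data, which makes the adjustment stricter. The simulated libraries also shared no RNA samples. These rates therefore do not carry over to the real fit.

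Shares of counts, numbers of detected genes, the spread within a kit and correlations of expression with gene length were compared by an exact two-sided permutation test over the 70 splits of the libraries into 4 and 4, for which 0.0286 is the smallest possible p. A gene was detected with at least 5 reads after all libraries had been thinned, with a fixed seed, to 2354681 counts. The direction of called non-coding and protein-coding genes was compared with Fisher's exact test. Fixed gene lists, 32 in number, cover pan-neuronal genes, cholinergic, GABAergic, glutamate and monoamine signalling, the flp and nlp neuropeptides and insulin-like peptides, neuronal identity transcription factors, ciliated sensory and mechanosensory genes, chemoreceptors, body wall and pharyngeal muscle, intestine, hypodermis and cuticle, germline, major sperm proteins, glia, coelomocytes, gonadal sheath and excretory cells, ribosomal proteins, histones, mitochondrial protein-coding genes, mitochondrial and nuclear rRNA, spliced leader RNAs, linc and anr RNAs, named non-coding RNAs, microRNAs, and heat shock and stress genes. The 27 lists with at least 5 tested members were tested with camera of limma 3.58.1, on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. As an alternative, the correlation was estimated from the data without the replicate block. Differences between RNA samples that both kits share can add to that estimate. It was not made with the block.

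The lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule names the 6 protein-coding and the 6 non-coding genes with the largest log2(SoLo/SMARTseq), and as many with the smallest, among called genes with a mean of at least 10 CPM in the higher kit and no overlap between the 4 and 4 libraries. It also names, per list, up to 3 members with the highest mean CPM and the called member with the largest absolute log2 fold change, as well as rab-3, unc-17, eat-4, unc-25 and cat-1. It gave 136 genes, and the text prints the values of a part of these.

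The pairing of the libraries by number was checked, since the design states that each RNA sample went into both kits. Across protein-coding genes, deviations of same-numbered libraries from their kit means correlated at 0.77, 0.37, 0.37 and 0.33 for numbers 1 to 4, and with the stated design the numbers were taken to pair the libraries. Unlike numbers among 2 to 4 also correlated, at 0.19 to 0.36, and with RNA sample 1 left out numbers 2, 3 and 4 correlated at 0.20, 0.06 and 0.07 (mean 0.11, exact one-sided permutation p = 0.333). The values thus set number 1 apart, and for numbers 2 to 4 the pairing rests on the design. The mean of 0.46 was reached by 2 of the 24 ways to match the libraries (exact one-sided permutation p = 0.0833), because an exchange of numbers 3 and 4 gave a slightly higher mean. Chi-square tests of pairs of libraries within a kit found a chi-square per degree of freedom of at least 1.66 in every pair, and no library was treated as a copy of another. As reads are not independent molecules, such values do not show that the RNA samples were separate. Pairs among SoLo libraries 2 to 4 had 1.66 to 2.40, and pairs with SoLo library 1 had 33.7 to 38.3. Whether RNA samples 2 to 4 are independent of each other stays open. Alternatives were other normalisations, filters and tools (among them DESeq2 1.42.0), a replicate block, a test against a 2-fold change, other detection thresholds and each library left out in turn. Added after the data were seen were fits without RNA sample 1 in either kit and with the counts of RNA samples 2 to 4 summed. Results restricted to genes free of exon overlap or without pseudogenes, and the sign-flip test of the spread over pairs, were also added then. For these restrictions the calls of the main fit were counted again without a refit. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for the remaining steps. GC content was not analysed here.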

Results

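The data were gene counts of 8 RNA sequencing libraries from sorted C. elegans neurons. RNA of 4 samples had each been divided between the SoLo Ovation kit, a ribodepletion approach, and the SMARTseq V4 kit, which primes on poly(A) tails. The design thus addresses which genes and classes of RNA each kit measures in the same RNA. SoLo libraries 1 to 4 held 2985097, 2354681, 3454199 and 2419523 gene counts, and SMARTseq libraries 1 to 4 held 7099497, 5342316, 6723049 and 4510927. Fold changes are given as log2(SoLo/SMARTseq) ± SE from edgeR, so that positive values are higher in SoLo, with n = 4 libraries per kit.

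Small nucleolar, small nuclear and transfer RNAs were far more abundant in the SoLo libraries. Small nucleolar RNAs, guides of RNA modification, took 0.502% ± 0.0947 (SD, n = 4) of SoLo counts and 0.0171% ± 0.00167 of SMARTseq counts, a ratio of 29.5. Small nuclear RNAs of the spliceosome and of trans-splicing took 0.0946% ± 0.02 and 0.00498% ± 0.00115, and transfer RNAs 0.0121% ± 0.00431 and 0.00105% ± 0.000302. The shares of the microRNA and piRNA biotypes were small and differed less, 0.00778% ± 0.000543 against 0.00523% ± 0.000614 and 0.0297% ± 0.00379 against 0.0195% ± 0.0034. Of the tested snoRNA genes 106 were higher in SoLo, 8 in SMARTseq and 5 in neither, and of 24 snRNA genes 22 were higher in SoLo and 1 in SMARTseq. The median log2 fold change was 7.05 over snoRNA genes and 7.89 over snRNA genes, or 6.39 and 6.66 with genes at 0 reads set to their bound. The kits did not part in this way for long intergenic RNAs, which took 0.163% ± 0.0139 of SoLo counts and 0.178% ± 0.0113 of SMARTseq counts (exact permutation p = 0.143, 0.151 after adjustment). Of 48 lincRNA genes, 4 were higher in SoLo and 27 in SMARTseq.

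Ribosomal RNA was on average still the largest non-coding class in both kits, although in SMARTseq library 1 it took 1.33% and the ncRNA biotype 1.34%, and it was higher in SoLo. It took 8.02% ± 1.43 (SD, n = 4) of SoLo counts and 1.66% ± 0.225 of SMARTseq counts. Most of it came from rrn-3.1, the 26S rRNA gene at chromosome I 15064838 to 15068346, with 7.24% ± 1.33 and 1.41% ± 0.222. All non-coding genes together held 11.09% ± 1.16 of SoLo counts and 3.55% ± 0.173 of SMARTseq counts. Without rRNA, the shares were 3.07% ± 0.431 and 1.89% ± 0.396. Mitochondrial genes took 2.33% ± 0.464 and 1.29% ± 0.237. For each of these shares, and for snoRNA, snRNA, tRNA, microRNA and piRNA, the exact two-sided permutation p was 0.0286, the smallest that 4 against 4 libraries allow, and 0.0396 after Benjamini-Hochberg adjustment over 18 classes. With the numbers as pairs, the exact sign-flip test gave 0.125, the smallest p that 4 pairs allow.

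**Figure D1:**
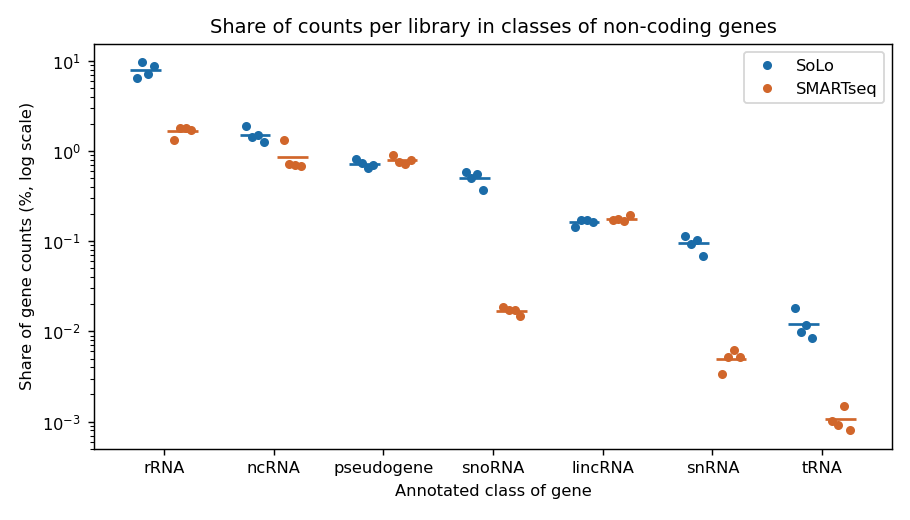
Share of each library's gene counts (percent, log axis) in 7 annotated classes of non-coding genes; each point is 1 library, lines are means of 4 libraries, SoLo in blue and SMARTseq in orange. The snoRNA share averaged 0.502% in SoLo and 0.0171% in SMARTseq, while the lincRNA shares of 0.163% and 0.178% lay close together.

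Among single non-coding genes, the RNA component of RNase P, rpr-1 (chromosome I 13463955 to 13464207), had 686 ± 106 CPM (SD, n = 4) in SoLo and 3.17 ± 0.794 CPM in SMARTseq. Its log2 fold change was 7.72 ± 0.25 (edgeR adjusted p = 4.32e-07). That of mrpr-1, the RNA component of RNase MRP, was 7.69 ± 0.60. In contrast tts-1, a long non-coding RNA, differed by less than its error at -0.01 ± 0.53. The 6 non-coding genes with the largest fold changes were C18A3.18, F31C3.15, F46F11.12, F46A8.13, F31C3.16 and F31C3.13. C18A3.18 had 914 ± 117 CPM in SoLo and 0 reads in SMARTseq, at least 5976-fold higher. F31C3.15 was at least 2045-fold, the snoRNA F46F11.12 at least 1218-fold, F46A8.13 at least 1272-fold and F31C3.13 at least 849-fold higher in SoLo. Without SoLo library 1, the library with most F46A8.13 reads, F46A8.13 was at least 401-fold higher. F31C3.16 had 6547 reads in SoLo and 1 in SMARTseq, a ratio of 9493 with an interval of 1703 to 375010. Its only SMARTseq read was in library 2, without which it was at least 2476-fold higher in SoLo. For a gene of equal abundance, 4 and 4 libraries do not overlap by chance in 2.86% of cases. F31C3.13, F31C3.15 and F31C3.16 lie at chromosome I 15060861 to 15070580 with 100%, 100% and 97.0% of their exon bases under rRNA genes or an rRNA pseudogene on the opposite strand. C18A3.18 likewise lies under C18A3.16 on the opposite strand. On its own strand 64.5% of its exon bases lie under exons of other genes, and it shares 80 bases with the span of rab-3. The source of the SoLo reads of C18A3.18 and the F31C3 genes is thus uncertain. Whether SMARTseq reads over the shared bases were counted for them is not known either, as the strand setting is not given. Their bounds and ratio may therefore reflect the counting as well as the kits.

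Of 527 non-coding genes tested, 260 were higher in SoLo and 135 in SMARTseq. Among called genes, 65.8% of non-coding and 39.8% of protein-coding genes were higher in SoLo (Fisher's exact test, two-sided, odds ratio 2.91, p = 1.56e-23, across genes, which are not independent replicates). The 6 non-coding genes with the largest fold changes towards SMARTseq were H22K11.5, T01H3.6, R03A10.8, C23H4.12, T12B3.9 and W02C12.4. H22K11.5 had 229 reads in SMARTseq and 0 reads in SoLo, at least 52.6-fold higher in SMARTseq. W02C12.4 had 33 ± 20.1 CPM in SMARTseq and 0.532 ± 0.454 CPM in SoLo. The ratios (SoLo over SMARTseq, with intervals) of the other 4 were 0.00381 (9.61e-05 to 0.0213) for T01H3.6, 0.00662 (0.000167 to 0.0373) for R03A10.8, 0.00991 (0.00204 to 0.0291) for C23H4.12 and 0.0102 (0.00123 to 0.0374) for T12B3.9. The only SoLo read of T01H3.6 was in library 4 and that of R03A10.8 in library 1, without which they were at least 68.9-fold and at least 36.8-fold higher in SMARTseq. The ratio of T12B3.9 was 0.00651 (0.000164 to 0.0366) without SoLo library 4. Of the 6, H22K11.5, R03A10.8, C23H4.12 and W02C12.4 lie whole inside a protein-coding gene on the opposite strand, which is irk-1, flp-32, cab-1 and hlh-30, so the source of their reads is uncertain. The count of non-coding genes higher in SoLo was 590 with DESeq2, 683 without a filter on low counts, 100 among genes with at least 50 reads in 4 libraries, 156 among genes with no exon overlap and 446 with RNA samples 2 to 4 summed and the replicate block. In these settings 18699, 27561, 6850, 7447 and 14456 genes of all classes were counted, against 11378 in the main fit.

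In the families of non-coding genes fixed by name, 5 of 6 tested genes with rrn names were higher in SoLo. The other, the 5.8S gene rrn-2.1, was higher in SMARTseq, with -0.63 ± 0.12. Only 5 of the 6 had an annotated length, so this list by name is not the same as the annotated nuclear rRNA genes. The 5S gene rrn-4.15 had 6.62 ± 4.02 CPM in SoLo and 0 reads in SMARTseq, at least 46.4-fold higher. The list passed camera (median 2.30, adjusted p = 0.0271, but adjusted p = 0.706 with an estimated correlation). Both mitochondrial rRNAs were higher in SoLo, MTCE.33 by 2.19 ± 0.14 and MTCE.7 by 1.95 ± 0.16. Of 4 spliced leader RNA genes, 3 were higher in SoLo, sls-2.2 most with 7.27 ± 0.54, and a ratio of 286 (78.9 to 2372) without SMARTseq library 2. All 3 have 91.8% of their exon bases under a gene on the opposite strand, so their reads are uncertain. The gene higher in SMARTseq was sls-2.1, with 628 reads against 227 (edgeR adjusted p = 0.0164, and 0.06 without SoLo library 2). Of 4 named non-coding RNAs, 2 (rpr-1 and mrpr-1) were higher in SoLo and 0 in SMARTseq. The mean log2(CPM + 1) of these 4 was 7.17 in SoLo library 1 (6.30 to 6.49 in the other 3) and 3.12 in SMARTseq library 1 (2.53 to 2.65). Of 42 linc genes, 4 were higher in SoLo and 24 in SMARTseq (25 adjusted over the list alone), with linc-7 at -3.16 ± 0.19 and linc-167 at -4.18 ± 0.70. The linc list had a median of -1.29 (camera adjusted p = 0.0059, adjusted p = 0.533 with an estimated correlation). Of 4 anr genes, 1 was higher in SoLo and 2 in SMARTseq, the largest difference being that of anr-36 with 21.3 ± 3.56 CPM in SMARTseq and 2.46 ± 0.73 CPM in SoLo, though 76.9% of its exon bases lie under other genes, so its reads are uncertain. Of 7 microRNA genes, 2 were higher in each kit. mir-90 was at least 34.8-fold higher in SoLo, though 93.9% of its exon bases lie under K01F9.7 on the opposite strand, so its reads are uncertain, and let-7 differed by less than its error, -0.31 ± 0.62.

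At an equal depth of 2354681 counts, SoLo libraries had more detected non-coding genes, while no difference in protein-coding genes passed the test. SoLo libraries had 10936 ± 369 protein-coding genes (SD, n = 4) with at least 5 reads and SMARTseq libraries 10909 ± 369, a difference of 27.2 genes that was smaller than the spread between replicates (exact permutation p = 0.857). Of non-coding genes, 776.5 ± 97.9 were detected in SoLo and 512.5 ± 124 in SMARTseq (exact permutation p = 0.0286, sign-flip over pairs p = 0.125). At this depth 209 protein-coding genes were detected in all 4 SoLo libraries and in none of the SMARTseq libraries, and 160 the other way round. Of non-coding genes, 231 were found in this way in SoLo alone and 43 in SMARTseq alone. The protein-coding difference depended on the threshold, being 939 genes with at least 1 read (exact permutation p = 0.0571) and 128.5 with at least 10 reads, and was 237.8 at equal protein-coding counts. The non-coding difference was 1298, 186.5 and 302.5 genes in these settings. Without thinning, the deeper SMARTseq libraries had more protein-coding genes, 12720.5 ± 783 against 11314.5 ± 672. The non-coding difference then turned and did not pass the test, with 881 ± 189 in SoLo and 1020.8 ± 297 in SMARTseq (exact permutation p = 0.486). By number, SoLo was lower in every pair (exact sign-flip p = 0.125, the smallest possible).

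Of 11378 genes tested, 2276 were higher in SoLo and 3139 in SMARTseq, 42.03% of calls being higher in SoLo. With library totals as the only scaling, 4318 and 2388 genes were called, 64.4% higher in SoLo. That scaling moved the median log2 fold change of all genes from 0.01 to 0.56, and DESeq2 gave a median of 0.12. Fold changes are therefore relative to the bulk of genes under TMM. Protein-coding genes gave 1955 and 2957 of the calls. Against a 2-fold change, 838 and 2076 genes passed. With the counts of RNA samples 2 to 4 summed, 490 and 851 genes were called and 1310 of the 5415 calls were kept, and with the replicate block added 3310 and 3758 genes were called and 4996 calls kept. No called gene changed its sign in either fit. Among the genes described here, those no longer called after summing without the block were F46A8.7, F46A8.13, R03A10.8, W02C12.4, cab-1, egl-21, cha-1, glr-5, eat-4, tdc-1, lim-4, daf-19, dyf-3, mec-12, mec-7, mec-17, unc-54, unc-60, myo-2, vit-6, glh-1, cbd-1, lgc-26, rpl-7A, ctc-2, ndfl-4, rrn-2.1, sls-2.1, linc-167, hsp-70, hsp-16.41 and rab-3.

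The 6 protein-coding genes with the largest fold changes towards SoLo were magu-1, his-63, del-9, pop-1, nhr-119 and ZK121.2. The first, magu-1, at chromosome III 463925 to 471702, had 19.5 ± 5.78 CPM (SD, n = 4) in SoLo and 2 reads in all SMARTseq libraries together, a ratio of 187 with an interval of 51.3 to 1553. The histone gene his-63, a member of a family of near-identical copies, had 24.4 ± 6.28 CPM in SoLo and 0.2 ± 0.254 in SMARTseq. The TCF transcription factor pop-1 (chromosome I 2822243 to 2830311) had 31.8 ± 4.35 and 0.4 ± 0.474 CPM, with a log2 fold change of 6.32 ± 0.58 (edgeR adjusted p = 1.91e-05). The values of del-9 were 27.8 ± 2.58 and 0.312 ± 0.516 CPM and those of the nuclear receptor gene nhr-119 38.2 ± 6.37 and 0.743 ± 1.04. A single library moved several of these estimates by more than 1.5-fold. For the first 5 of them at most 3 SMARTseq reads were then left, so ratios (SoLo over SMARTseq) with their intervals are given. They were 338 (60.3 to 13398) for his-63 and 176 (60.04 to 858) for nhr-119 without SMARTseq library 3, 436 (77.8 to 17283) for del-9 and 169 (57.3 to 820.5) for pop-1 without SMARTseq library 4, and 293 (52.1 to 11606) for magu-1 without SMARTseq library 2. The log2 fold change of ZK121.2 was 5.50 ± 0.71 with all libraries, 4.82 without SoLo library 1 and 6.13 without SMARTseq library 1.

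The 6 with the largest fold changes towards SMARTseq were F46A8.7, B0294.3, F35C8.8, E02H9.6, M153.2 and D2062.6. F46A8.7, annotated at chromosome I 11238117 to 11238227, had 2084 ± 1858 CPM in SMARTseq and 4.3 ± 6.43 CPM in SoLo, with a log2 fold change of -8.88 ± 1.17 (edgeR adjusted p = 0.000212). It was -10.79 without SoLo library 1 and -8.03 without SMARTseq library 1, and with RNA samples 2 to 4 summed the log2 fold change of F46A8.7 was -8.60 and not called (edgeR adjusted p = 0.0532). B0294.3 had 143 ± 114 and 0.952 ± 0.558 CPM, with -7.17 ± 0.67, and -6.46 without SMARTseq library 1. E02H9.6 had 31 ± 6.4 and 0.356 ± 0.349 CPM, with -6.28 ± 0.51, and without SoLo library 1, which left 2 SoLo reads, a ratio of 0.00643 (0.000777 to 0.0233). M153.2 had 58.6 ± 5.47 and 0.883 ± 0.975 CPM, with -5.91 ± 0.55, and -6.76 without SoLo library 1. D2062.6 had 273 reads in SMARTseq and 3 in SoLo, a ratio (SoLo over SMARTseq) of 0.0159 with an interval of 0.00327 to 0.0471. F35C8.8 had 234 and 1, a ratio of 0.0062 with an interval of 0.000156 to 0.0349. Without SoLo library 3, the ratio of D2062.6 was 0.00768 with an interval of 0.000194 to 0.0432, and F35C8.8, whose only SoLo read was in that library, was at least 37.2-fold higher in SMARTseq. Of F35C8.8, 94.2% of the exon bases lie under jkk-1 on the opposite strand, so its reads are uncertain.

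Pan-neuronal genes as a list were higher in SoLo, while 2 of the 3 most abundant members went the other way. Of 33 tested members 20 were higher in SoLo and 6 in SMARTseq (21 and 6 adjusted over the list alone), with a median of 0.61, or 0.11 with the trend of gene length taken out. The list passed camera (adjusted p = 0.0188, but adjusted p = 0.481 with an estimated correlation). rab-3, a synaptic vesicle GTPase whose promoter drives the sorting reporter, had 1353 ± 83.8 CPM (SD, n = 4) in SoLo and 703 ± 124 CPM in SMARTseq, a log2 fold change of 0.95 ± 0.15 (edgeR adjusted p = 0.000771). The syntaxin gene unc-64 was higher in SoLo by 3.75 ± 0.19. Lower in SoLo were cab-1 with -2.05 ± 0.23 and egl-21, a neuropeptide-processing carboxypeptidase, with -1.57 ± 0.20. For egl-3, a proprotein convertase, the value was 0.49 ± 0.22 (adjusted p = 0.101), which passed with the replicate block (adjusted p = 1.2e-05) and without SMARTseq library 1 (0.0124).

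Genes of transmitter systems differed between the kits gene by gene. Of 5 GABAergic genes, 4 were higher in SMARTseq and 1 in SoLo, with a median of -3.03. unc-25, the glutamate decarboxylase of GABA neurons, had 744 ± 22.5 CPM in SoLo and 6696 ± 501 CPM in SMARTseq (-3.17 ± 0.12), and the vesicular protein gene unc-46 and the transcription factor gene unc-30 had -3.05 ± 0.15 and -3.03 ± 0.18. The list passed camera with an adjusted p of 0.0348. The adjusted p was 0.0783 with the replicate block, 0.0587 without RNA sample 1 and 0.533 with an estimated correlation. Of 6 cholinergic genes, 2 were higher in SoLo and 1 in SMARTseq (adjusted p = 0.594). The vesicular acetylcholine transporter gene unc-17 was near 0 (-0.08 ± 0.13, adjusted p = 0.642), although it was called at 0.46 with library totals as the only scaling. The acetyltransferase gene cha-1, which shares its locus and exon bases with unc-17, so that its reads are uncertain, had -0.99 ± 0.13, and the acetylcholinesterase gene ace-2 had 4.36 ± 0.43. Of 17 glutamate signalling genes, 5 were higher in SoLo and 8 in SMARTseq (adjusted p = 0.594), with the vesicular glutamate transporter gene eat-4 at 0.93 ± 0.21 and the receptor subunit genes nmr-2 and glr-5 at -2.30 ± 0.17 and -1.01 ± 0.24. Of 10 monoaminergic genes, 1 was higher in SoLo (2 adjusted over the list alone) and 4 in SMARTseq (adjusted p = 0.594). The vesicular monoamine transporter gene cat-1 had -0.06 ± 0.22 and the tyramine and octopamine synthesis genes tdc-1 and tbh-1 had -1.68 ± 0.16 and -2.07 ± 0.23. Of tbh-1, 18.2% of the exon bases lie under exons on the opposite strand, so its reads are uncertain. The medians of the glutamate and monoamine lists, -0.38 and -0.26, became 0.16 and 0.27 with library totals as the only scaling.

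Chemoreceptor, insulin-like peptide, mechanosensory and identity transcription factor genes were lower in SoLo as lists. Of 127 tested chemoreceptor genes, 56 were higher in SMARTseq and 2 in SoLo (54 and 2 adjusted over the list alone), with a median of -2.16. Of 23 insulin-like peptide genes, 15 were higher in SMARTseq and 0 in SoLo, with a median of -2.21. Of 12 mechanosensory genes, 8 were higher in SMARTseq (9 adjusted over the list alone) and 0 in SoLo, with a median of -1.78, and of 31 neuronal identity transcription factor genes 18 and 6 (19 and 7 adjusted over the list alone), with a median of -1.48. The camera adjusted p values of these 4 lists were 0.000374, 0.000597, 0.00837 and 0.00837. With an estimated correlation the adjusted p values were 0.814, 0.735, 0.735 and 0.706. The tubulin genes of touch receptor neurons, mec-12 and mec-7, had 15190 ± 5240 and 8926 ± 3424 CPM (SD, n = 4) in SMARTseq against 2250 ± 887 and 1116 ± 478 CPM in SoLo. The tubulin acetyltransferase gene mec-17 had -3.47 ± 0.39. Among identity factors, ast-1 had -3.46 ± 0.30, unc-86 -2.36 ± 0.18 and lim-4 -3.83 ± 0.52. Among peptides and receptors, ins-28 had -1.61 ± 0.15, ins-23 -4.82 ± 0.21, sre-23 -2.89 ± 0.34 and srt-24 -4.43 ± 0.59. In both kits, library 1 lay farther from the other 3 in these lists than they did from each other. The mean log2(CPM + 1) of chemoreceptor genes was 2.95 in SoLo library 1 (1.92 to 1.95 in the other 3) and 4.45 in SMARTseq library 1 (3.02 to 3.09), that of insulin-like peptide genes 5.63 (4.05 to 4.30) and 7.43 (6.14 to 6.21), that of mechanosensory genes 5.71 (6.50 to 6.67) and 7.25 (8.07 to 8.21), and that of identity factors 5.54 (5.17 to 5.27) and 6.70 (6.12 to 6.36). With the replicate block, 82 chemoreceptor genes were higher in SMARTseq and 4 in SoLo, and 2 insulin-like genes and 1 mechanosensory gene were higher in SoLo. Without RNA sample 1, 59 chemoreceptor genes were higher in SMARTseq and 9 in SoLo.

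Ciliated sensory genes did not pass the list test. Of 34, 14 were higher in SMARTseq and 1 in SoLo (14 and 0 adjusted over the list alone), with a median of -1.31 (camera adjusted p = 0.052, and 0.823 with an estimated correlation). With the replicate block 22 and 6 were called and the list's adjusted p was 0.0135, and it was 0.0163 without RNA sample 1. Leaving out SoLo library 1 gave 0.00314, and SMARTseq library 2, 3 or 4 gave 0.038, 0.03 and 0.0262. It was 0.124, 0.164 and 0.162 without SoLo library 2, 3 or 4, and 0.293 without SMARTseq library 1. The mean log2(CPM + 1) of the list was 5.195 in SoLo library 1 (3.26 to 3.34 in the other 3) and 6.27 in SMARTseq library 1 (4.03 to 4.40). daf-19, the transcription factor gene of ciliated neurons, had -1.24 ± 0.21, and the ciliary gene dyf-3 -3.55 ± 0.57, and -4.16 without SoLo library 1. The flp and nlp neuropeptide genes were split. Of 30 flp genes 11 were higher in SoLo (12 adjusted over the list alone) and 12 in SMARTseq, and of 37 nlp genes 8 and 12, or 14 and 12 with the replicate block. Their camera adjusted p values were 0.474 and 0.675. Genes of the flp list had a mean log2(CPM + 1) of 9.09 in SoLo library 1 (8.59 to 8.699 in the other 3) and 9.51 in SMARTseq library 1 (9.09 to 9.24). Their medians of 0.00 and 0.13 and their means of -0.50 and -0.42 differ in sign, camera giving the direction of the means. Of the 3 most abundant members of each of these lists, 5 of 6 were higher in SMARTseq, among them flp-1 with -1.69 ± 0.12 and nlp-21 with -2.30 ± 0.13. flp-32 had -3.25 ± 0.13, and nlp-18, the 1 of the 6 that was not called, 0.15 ± 0.13 (adjusted p = 0.37).

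**Figure D2:**
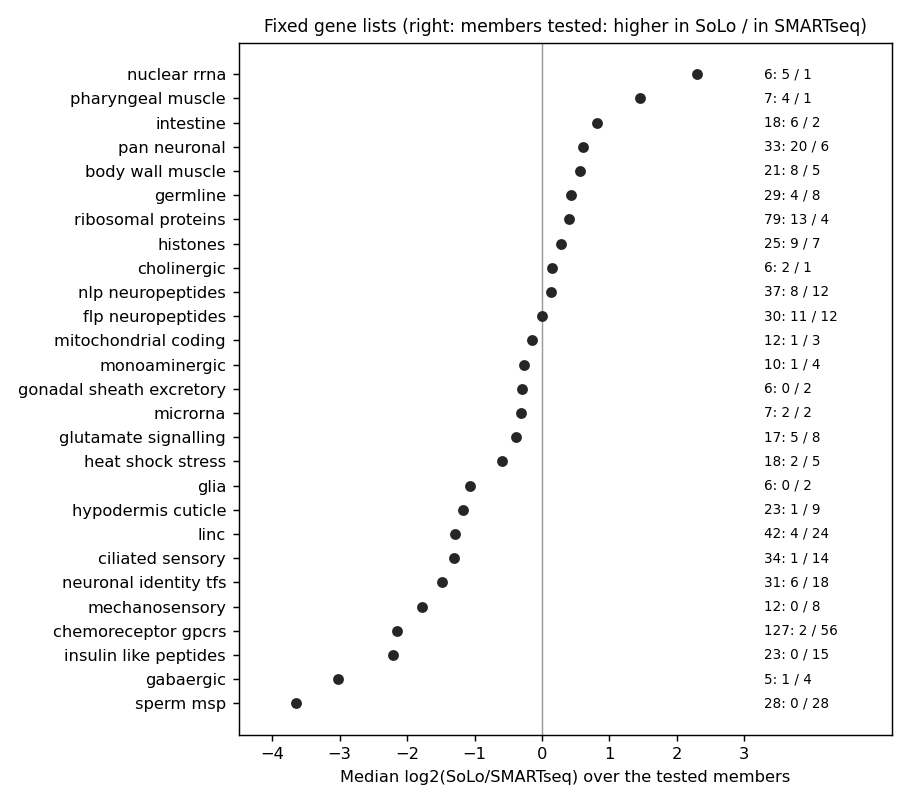
Median log2(SoLo/SMARTseq) over the tested members of each fixed gene list with at least 5 tested members; numbers at the right give members tested, then members called higher in SoLo and in SMARTseq by edgeR. Medians run from -3.65 for major sperm proteins to 2.30 for the nuclear rrna list, which holds genes with rrn names.

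Reads of marker genes of other cell types were present in the libraries of both kits, and whether they came from such cells was not tested. All 28 tested major sperm protein genes, short genes in near-identical copies whose reads are uncertain, were higher in SMARTseq, with a median of -3.65 (camera adjusted p = 1.88e-08, adjusted p = 0.706 with an estimated correlation). msp-40 had 135 ± 62.2 CPM (SD, n = 4) in SMARTseq and 10.2 ± 5.69 in SoLo, and msp-38 had -4.58 ± 0.67. Of 23 hypodermis and cuticle genes 9 were higher in SMARTseq and 1 in SoLo, or 11 and 2 with the replicate block. The collagen gene col-140 had -3.76 ± 0.22. The camera adjusted p of the list was 0.221, and 0.175 with the replicate block. Without the block it was 0.0266 without SMARTseq library 1 and 0.0479 without RNA sample 1. The mean log2(CPM + 1) of this list was 3.27 in SoLo library 1 (4.202 to 4.28 in the other 3) and 3.75 in SMARTseq library 1 (5.27 to 5.74). Of 21 body wall muscle genes 8 were higher in SoLo (9 adjusted over the list alone) and 5 in SMARTseq (adjusted p = 0.228), with a median of 0.57, or 0.13 with the trend of gene length taken out. The myosin gene unc-54 had 6255 ± 769 CPM in SoLo and 3891 ± 778 CPM in SMARTseq (0.68 ± 0.17). The next most abundant member, lev-11, had only 265 ± 24.2 and 366 ± 48.9 CPM, so the level of unc-54 does not stand for the list. The cofilin gene unc-60 had 1.49 ± 0.15, and unc-22, which encodes the giant protein twitchin, had 5.14 ± 0.46, and 5.81 without SMARTseq library 3. Of 7 pharyngeal muscle genes 4 were higher in SoLo and 1 in SMARTseq (adjusted p = 0.0992), with the myosin genes myo-1 at 3.64 ± 0.50 and myo-2 at 1.71 ± 0.46. Of 18 intestine genes 6 were higher in SoLo and 2 in SMARTseq (adjusted p = 0.0917, and 0.0439 without SMARTseq library 1), with the yolk protein genes vit-2 and vit-6 at 2.78 ± 0.26 and 3.09 ± 0.42. Pharyngeal muscle genes had a mean log2(CPM + 1) of 4.32 in SoLo library 1 (3.62 to 3.915 in the other 3) and 3.33 in SMARTseq library 1 (2.43 to 2.65), and intestine genes of 4.51 (3.74 to 4.115) and 3.94 (3.099 to 3.31).

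Of 29 germline genes 4 were higher in SoLo and 8 in SMARTseq (adjusted p = 0.594, and 7 and 8 with the replicate block). Their median of 0.43 and their mean of -0.11 differ in sign, and camera gave the direction of the median. The helicase gene glh-1 had -2.16 ± 0.43 and the eggshell gene cbd-1 0.98 ± 0.25. Of 6 glia genes 0 were higher in SoLo and 2 in SMARTseq (5 with the replicate block), hlh-17 having -4.29 ± 0.30. The camera adjusted p of the glia list was 0.127, and 0.0969 with the replicate block. Of 2 tested coelomocyte genes 1, lgc-26, was higher in SMARTseq with -3.27 ± 0.66, and both were with the replicate block. Of 6 genes of the gonadal sheath and excretory list, 0 were higher in SoLo and 2 in SMARTseq (adjusted p = 0.621), with lim-7 at -2.34 ± 0.19. The median of that list, -0.29, became 0.24 with library totals as the only scaling.

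Ribosomal protein genes were slightly higher in SoLo as a list, but the number called depended on the fit. Of 79, 13 were higher in SoLo and 4 in SMARTseq (10 and 4 adjusted over the list alone). With the replicate block 52 and 8 were called, and 48 and 9 without RNA sample 1 and without the block. The median was 0.41, or 0.80 with the trend of gene length taken out (camera adjusted p = 0.0303, adjusted p = 0.86 with an estimated correlation). The mean log2(CPM + 1) of the list was 7.59 in SoLo library 1 (8.35 to 8.53 in the other 3) and 7.20 in SMARTseq library 1 (8.11 to 8.27). The adjusted p was 0.32 without SMARTseq library 1 and 0.0528 without SoLo library 4. The largest difference was in the opposite direction, rpl-12 with -2.97 ± 0.24, as was rpl-7A with -2.50 ± 0.39, while rla-0 had 0.07 ± 0.34. Of 25 histone genes 9 were higher in SoLo and 7 in SMARTseq (10 and 9 adjusted over the list alone), with camera adjusted p = 0.594. his-37 and his-41 had -2.77 ± 0.20 and -3.05 ± 0.15, and copies of histone genes share reads. Of 12 mitochondrial protein-coding genes 1 was higher in SoLo and 3 in SMARTseq (camera adjusted p = 0.677). The values of ctc-2 and ndfl-4 were -0.99 ± 0.19 and -1.87 ± 0.33. With the replicate block 3 and 5 of the 12 genes were higher in SoLo and SMARTseq (camera adjusted p = 0.701). Their mean log2(CPM + 1) was 8.92 in SoLo library 1 (9.68 to 9.74 in the other 3) and 9.21 in SMARTseq library 1 (9.84 to 9.96). Their median of -0.15 became 0.39 with library totals as the only scaling. Of 18 heat shock and stress genes 2 were higher in SoLo and 5 in SMARTseq (camera adjusted p = 0.621). With the replicate block 6 and 11 of them were higher in SoLo and SMARTseq (camera adjusted p = 0.239). Their mean log2(CPM + 1) was 5.92 in SoLo library 1 (8.08 to 8.20 in the other 3) and 6.66 in SMARTseq library 1 (8.78 to 9.15). hsp-16.41, a small heat shock protein gene, had -3.21 ± 0.78 and hsp-70 -2.51 ± 0.79 (adjusted p = 0.0256, and 0.0514 to 0.0619 when SoLo library 3 or 4 or SMARTseq library 2, 3 or 4 was left out). hsp-1 had 0.52 ± 0.36 (adjusted p = 0.258, and 1.62e-05 with the replicate block). For the microRNA list, adjusted p was 0.621, with a median of -0.31 and a mean of 1.10. In the lists for which no second count is given, the count adjusted over the list alone was the same.

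Longer protein-coding genes were relatively higher in SoLo. Across 10635 genes, which are not independent replicates, the Spearman correlation of exonic length with log2(SoLo/SMARTseq) was 0.30. The median log2 fold change was -0.46 in the shortest of 5 equal groups, with 105 to 837 exon bases, -0.41, -0.15 and 0.18 in the next 3, and 0.51 in the longest, with 2495 to 56044 bases. In the longest group 748 genes were higher in SoLo and 300 in SMARTseq, and in the shortest 234 and 805. Within libraries, the Spearman correlation of length with CPM was 0.30, 0.28, 0.27 and 0.27 in SoLo libraries 1 to 4 and 0.11, 0.06, 0.07 and 0.04 in SMARTseq libraries 1 to 4 (exact permutation p = 0.0286, the smallest possible).

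**Figure D3:**
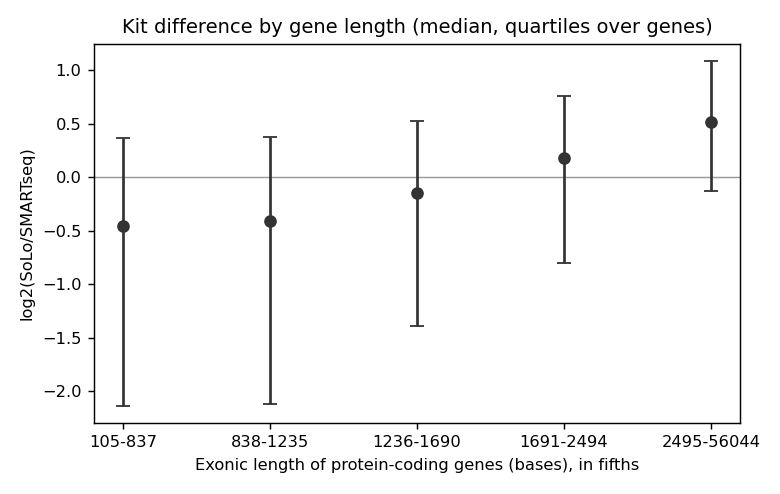
log2(SoLo/SMARTseq) of protein-coding genes in 5 groups by exonic length in bases; points are medians over genes and bars reach from the lower to the upper quartile. The medians lie at -0.46 in the shortest group and 0.51 in the longest.

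Replicates of a kit were spread less in SoLo than in SMARTseq, without passing the test. The biological coefficient of variation over protein-coding genes, from the common dispersion of edgeR within each kit, was 0.305 in SoLo and 0.498 in SMARTseq. The median absolute log2 deviation of SoLo libraries 1 to 4 from their kit mean was 0.322, 0.174, 0.161 and 0.174, and that of SMARTseq libraries 1 to 4 was 0.442, 0.276, 0.253 and 0.287. The difference of the kit means of these values was -0.107 (exact permutation p = 0.114). By number, the differences were -0.12, -0.102, -0.0922 and -0.113, lower in SoLo in 4 of 4 pairs (exact sign-flip p = 0.125, the smallest possible). Library 1 lay farthest from its kit's mean in both kits. Without RNA sample 1, the coefficients of variation were 0.0615 and 0.326, and the difference of the deviations was -0.0913 (exact permutation p = 0.1, the smallest that 3 against 3 libraries allow). Without SMARTseq library 1 alone the difference was 0.00314. The deviations of the 2 libraries numbered 1 correlated at 0.77 across genes, and those of numbers 2, 3 and 4 at 0.37, 0.37 and 0.33, against 0.19 to 0.36 for unlike numbers among 2 to 4. With RNA sample 1 left out, numbers 2, 3 and 4 correlated at 0.20, 0.06 and 0.07.

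**Figure D4:**
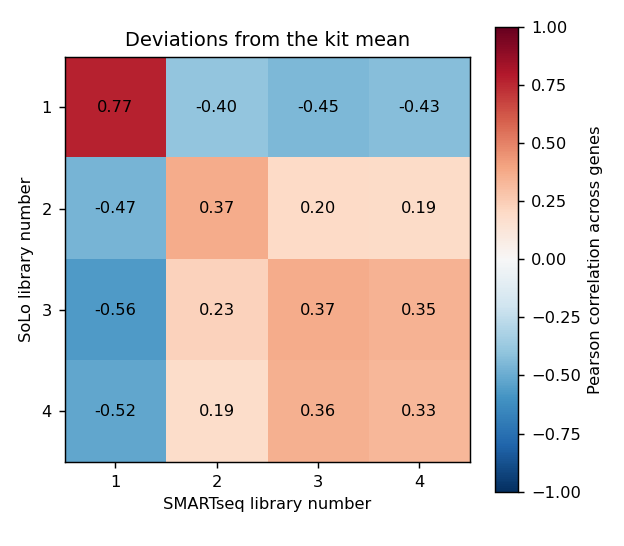
Pearson correlation, across 10635 protein-coding genes, between the deviations of each SoLo library (rows) and each SMARTseq library (columns) from the mean of their kit. The 2 libraries numbered 1 correlate at 0.77, other same-numbered libraries at 0.37, 0.37 and 0.33, unlike numbers among 2 to 4 at 0.19 to 0.36, and library 1 with another number at -0.56 to -0.40.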

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

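The test of whether RNA sample 1 was altered after the RNA had been divided was chosen only after the result was seen, as were the tests with genes free of exon overlap. A value of 1 library that lay far from the other 3 of its kit, by the ratio of its gap to the whole range (Dixon's test), is listed here. That test was applied to 240 groups of 4 libraries. Chance alone gives such a value in 5% of groups of independent, normally distributed values. The groups here share libraries, and many genes were named for large differences. A gene with reads in only 1 library of a kit is flagged by construction. The number found is therefore not compared with that rate. It found 47.

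Of the shares of counts, in SMARTseq library 1 non-coding genes took 3.81% (95% interval 3.79 to 3.82, against 3.44 to 3.50% in the other 3) and non-coding genes other than rRNA 2.48% (2.47 to 2.49, against 1.64 to 1.72%). Nuclear rRNA took 1.23% there (1.23 to 1.24, against 1.63 to 1.70%), all rRNA 1.33% (1.32 to 1.34, against 1.73 to 1.80%), rrn-3.1 1.08% (1.07 to 1.09, against 1.49 to 1.54%) and the ncRNA biotype 1.34% (1.33 to 1.35, against 0.686 to 0.714%). In SoLo library 1, genes without an annotation match took 2.86% (2.84 to 2.88, against 3.72 to 3.78%) and mitochondrial genes 1.64% (1.63 to 1.65, against 2.52 to 2.64%). The median absolute log2 deviation from the kit mean was 0.322 in SoLo library 1, against 0.161 to 0.174.

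In SoLo library 1, with the range of the other 3 libraries of the kit in parentheses, CPM values were magu-1 10.809 (22 to 22.8), ZK121.2 259 (60.9 to 82.7), F46A8.7 13.9 (0 to 2.14), F46A8.13 561 (55.3 to 67.4), R03A10.8 0.277 (0 in each) and eat-4 269 (215 to 220). SoLo library 1 also had cab-1 4789 (2473 to 2670), egl-21 5282 (3089 to 3339), egl-3 8982 (5498 to 5792), nmr-2 39.6 (55.2 to 56.7), dyf-3 24.9 (6.42 to 8.94) and mec-12 931 (2580 to 2860). Further values of SoLo library 1 were mec-7 402 (1293 to 1397), mec-17 264 (691 to 765), tts-1 112 (30.7 to 42.8), let-7 1.11 (9.27 to 10.1), hsp-16.41 54 (611 to 686) and hsp-1 1405 (3257 to 3443).

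In SMARTseq library 1, CPM values were F46A8.7 4870 (1111 to 1212), B0294.3 313 (75.9 to 92.9), rab-3 519 (743 to 788), egl-3 6562 (3797 to 4262), ast-1 2221 (1222 to 1281) and lim-4 1114 (398 to 411). SMARTseq library 1 also had dyf-3 279 (75.1 to 105), rpl-7A 1134 (2888 to 3137), rla-0 713 (1765 to 1847), ctc-2 2235 (3170 to 3278) and linc-167 11.124 (3.71 to 4.73). Of the other libraries, SMARTseq library 4 had del-9 1.08 (0 to 0.171), SMARTseq library 3 had nhr-119 2.3 (0.171 to 0.269), SoLo library 3 had F35C8.8 0.242 (0 in each), SMARTseq library 2 had F31C3.16 0.236 (0 in each), SoLo library 4 had T01H3.6 0.349 (0 in each), SoLo library 4 had tbh-1 39.8 (52.2 to 54.6), SMARTseq library 3 had unc-22 8.66 (2.36 to 2.96), SMARTseq library 3 had MTCE.33 803 (779 to 783) and SoLo library 2 had mir-90 2.85 (5.82 to 6.29).

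Library 1 stood apart from libraries 2 to 4 in both kits, in 1149 of 10635 protein-coding genes in SoLo and 799 in SMARTseq. Of these, 272 were shared, all in the same direction, where 86.3 would be shared if the kits were independent. Sequencing depth was argued against, since at equal depth, in each kit, the lowest chi-square per degree of freedom of a pair with library 1 was still at least 8.04 times the highest of a pair of the same kit without it. A fault in library preparation or sequencing of a single library was argued against by the correlation of 0.77 between the deviations of the 2 libraries numbered 1, which were prepared with different kits. A cause after the division that both libraries numbered 1 shared is not excluded, since it could give such a correlation too. What set RNA sample 1 apart, before or after the RNA was divided, stays open. No biological explanation was tested, since the labels name none.

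Some genes were read by 1 kit and almost not by the other, and no biological explanation was tested, since the same RNA went into both kits. Called protein-coding genes were taken as low in SMARTseq with a log2 fold change of at least 4. A mean of at least 10 CPM in SoLo was also asked. This gave 54 genes, whose median log2 fold change of 4.55 follows from the cut. A loss of reads over exons shared with an opposite-strand gene was argued against. The median of the 12 coding genes with at least 50% of their exon bases under such a gene differed from that of 7080 genes with no exon overlap by -0.34 (95% interval -2.63 to 0.93). Of the 54 genes, 46 had no opposite-strand exon overlap at all. The trend with gene length was argued against as the whole cause, as the longest group of all protein-coding genes reached a median of only 0.51, with an upper quartile of 1.08. The median of the 54 was 4.35 with the trend taken out. Their choice by fold change largely set this value in advance, so it is no separate support. Of non-coding genes higher in SMARTseq, 19.26% lay inside an opposite-strand protein-coding gene, against 10.38% of those higher in SoLo (Fisher's exact test, odds ratio 2.06, p = 0.019, across genes), so reads of the opposite gene may be counted for some of them, as the SMARTseq chemistry does not mark the strand. Inside a same-strand protein-coding gene lay 42.31% of the non-coding genes higher in SoLo and 11.85% of those higher in SMARTseq (Fisher's exact test across genes, odds ratio 0.183, p = 1.85e-10, and for the ncRNA biotype alone 26.67% and 16% with p = 0.208), so reads of the host gene stay open as a source of SoLo counts.

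Longer protein-coding genes were higher in SoLo. Reads over exons shared with an opposite-strand gene were argued against as the whole cause, since the correlation was 0.33 among genes with no exon overlap, and so were low counts of short genes, since it was 0.22 among genes with at least 50 reads in all 8 libraries. Length alone was argued against as the cause of the medians of 3 lists, which were still -1.64 for insulin-like peptides, -1.50 for chemoreceptors and -2.46 for major sperm proteins with the trend taken out. For other lists the same step went both ways, the medians of pan-neuronal and body wall muscle genes going from 0.61 to 0.11 and from 0.57 to 0.13, but those of ribosomal protein, histone and flp genes from 0.41 to 0.80, 0.28 to 0.86 and 0.00 to 0.49, and that of glutamate genes from -0.38 to -0.87, so no part of these medians is assigned to length. Priming from the poly(A) tail and fragmentation differ between the kits and stay open, as GC content and the position of reads along genes were not tested, nor was any biological explanation.

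Other divisions of the 8 libraries into 4 and 4 were counted, 35 in all. For genes called by edgeR, 1 of the 35, the division by kit, reached its 5415 calls, the highest other having 0 (6213 and at most 1369 at an unadjusted p under 0.05). This share met the limit set beforehand for chance, but only with the pairing ignored. Only 8 divisions part all 4 numbered pairs, too few for a share below that limit. Every other division mixes the kits, so a kit difference adds to the spread within its groups. Chance is therefore not excluded by these counts. The same held for non-coding genes, with 395 calls, the highest other having 0 and 1 of 35 divisions as large. For the gene lists chance cannot be excluded either. At least 10 lists were called by 4 of the 35 divisions, the highest 13, and 29 divisions other than that by kit called at least 1. Many of the 29 hold 3 libraries of 1 kit in each group, so the kit still acts in them. The 3 others with at least 10 lists hold 2 libraries of each kit in each group, and both libraries numbered 1 lie in the same group. A structure of the samples besides the kit may thus add to the calls. So may the preset correlation, since 0 lists passed with an estimated correlation, though that estimate ignored the pairing. Among the 8 divisions that part all 4 numbered pairs, the highest other had 590 genes at an unadjusted p under 0.05 and 9 lists.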

How the results depend on the processing

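Fits without RNA sample 1 and with RNA samples 2 to 4 summed were chosen only after the result was seen. So were the restrictions to genes free of exon overlap and without pseudogenes, and the sign-flip test of the spread. For the changes below the cause was not tested, except where the construction is named. Genes higher in SoLo numbered 4318 with library totals alone, 838 against a 2-fold change, 490 with RNA samples 2 to 4 summed and 1464 among genes with no exon overlap, and 1934 to 2699 when single libraries were left out. Genes higher in SMARTseq numbered 2076, 851 and 2034 in the last 3 of these settings, and 2864 to 3393 when single libraries were left out. The counts among genes with no exon overlap are calls of the main fit over 7447 of its 11378 genes, without a refit. They are therefore lower by construction. With samples summed and the replicate block, 3310 and 3758 genes were higher in SoLo and SMARTseq, so the low counts belong to summing without the block. Non-coding genes higher in SoLo numbered 590 with DESeq2, 683 without a filter, 100 with at least 50 reads in 4 libraries, 446 with samples summed and the replicate block, 156 with no exon overlap, and 264 to 302 when single libraries were left out. DESeq2 tested 18699 genes, the fit without a filter 27561 and that with at least 50 reads 6850. With samples summed 14456 genes were tested, against 11378 in the main fit. These counts thus also follow the number of genes tested. Of the lists, 0 passed camera with an estimated correlation (1 at an unadjusted p under 0.05), 19 passed fry, and 10 to 12 passed camera when single libraries were left out.

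The difference in the non-coding share, 7.54 points, had p = 0.125 in the exact sign-flip test, was 7.95 without RNA sample 1 and 7.03 to 7.86 when single libraries were left out. The difference in detected protein-coding genes was -1406 without thinning, and -153.7 to 195.2 when single libraries were left out. That in non-coding genes was -139.8 without thinning, 264 with p = 0.125 in the exact sign-flip test, 276 without RNA sample 1 and 215.8 to 324.2 when single libraries were left out. SMARTseq libraries are deeper, so counts without thinning follow depth. The matching of the samples scored 0.57 with at least 50 reads in all 8 libraries (exact permutation p = 0.0417, the smallest possible) and 0.11 without RNA sample 1 (exact permutation p = 0.333). The length correlation was 0.32 without RNA sample 1 and 0.29 to 0.33 when single libraries were left out, and the difference in spread -0.201 to 0.00314, and -0.107 with p = 0.125 in the exact sign-flip test over pairs (the replicate block). By construction, exact permutation p cannot fall below 0.0571 with 3 against 4 libraries, 0.1 with 3 against 3 and 0.125 in the sign-flip test. With library totals alone, unc-17 turned to 0.46 and lev-11 to 0.08. Leaving out single libraries changed the call of 11 of 136 named genes, and summing weakened 47, of which none changed sign. The replicate block gave 3290 genes higher in SoLo and 3664 in SMARTseq. Beyond the values printed beside the results, it changed the call of no other list or gene named in the report.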

Other observations

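Only values that were noted after the data were seen stand in this part, and none of them was tested. RNA sample 1 differed from the other 3 in sensory, heat shock and cuticle genes, among others, and in the same direction with both kits. Pan-neuronal genes had nearly equal levels only as a list mean, with a mean log2(CPM + 1) of 8.90 in SoLo library 1 (8.82 to 8.89 in the other 3) and 8.46 in SMARTseq library 1 (8.34 to 8.41). Single members went both ways. The CPM of egl-3 was higher in SoLo library 1 (8982 against 5498 to 5792) and in SMARTseq library 1 (6562 against 3797 to 4262). That of rab-3 was lower in SMARTseq library 1 (519 against 743 to 788).

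F46A8.13 and F46A8.7, which are 136 bases apart on chromosome I and lie on opposite strands, were read by opposite kits. The first had 2632 reads in SoLo and 0 in SMARTseq, and the second 61 and 44126. C18A3.18 shares 80 bases with the span of rab-3 on the same strand, and had 12365 reads in SoLo and 0 in SMARTseq, whereas rab-3 had 18034 and 13382.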
